A study of Drosophila melanogaster with 30 samples.

How the data were processed

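Single male flies of the Cantonized w1118 strain were raised at 25 °C and 60% humidity in 12 h of light and 12 h of dark, and were collected at 5 or 25 days of age after a sleep assay that picked out the individuals with fragmented sleep, per the labels. Head and body of each fly were extracted singly with Trizol, mRNA was purified with oligo d(T) beads, and libraries were made with the NEBNext Ultra II kit and sequenced on a HiSeq X. The study design text says that the authors trimmed adapters with Trimmomatic, mapped the reads to dm6 from UCSC with STAR, removed alignments with a mapping quality below 8 and non-primary alignments, counted reads on exons with HTSeq-count and compared groups with DESeq2 in R. Tool versions and the gene annotation behind the counts are not stated. The deposited count table holds raw counts of reads per gene, with no normalization, for 17559 genes in 30 libraries. The deposited DESeq2 table holds q values, a p value adjusted by the authors, and log2 fold changes of the authors' comparisons, and it lists only genes with a q of 0.05 or less. The direction of the log2 columns was checked against counts for the aged SF over aged NSF column of the heads, and the other columns follow the file header.

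Groups are the conditions of the sample titles in each tissue, 5 libraries each: young, aged NSF (normal sleep) and aged SF (fragmented sleep). All flies carry 1 batch date, so no batch could be compared. Replicate numbers recur in every group; nothing in the labels says that equal numbers mark the same fly or vial, so the main tests use no pairing. Total counts ranged from 1685034 to 3597530 in heads and from 2458538 to 8060238 in bodies. The floor for a gene with no reads was taken as 3 counts per library. Replicates were checked for copies of 1 library with a chi-square per degree of freedom of each pair, whose lowest value was 4.42, and none was a copy.

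Genes of 1 tissue were tested with edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr by group and a robust quasi-likelihood fit of the 3 groups, and each pair of groups was a contrast. Differences between tissues were tested as interaction contrasts in a fit of all 30 libraries. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Gene lists were tested with camera of limma 3.58.1 (preset correlation of 0.01) on log2 CPM with a prior count of 2, for lists with at least 5 tested members, and the p values were adjusted over the lists of 1 comparison. Medians, counts of members that rose or fell and counts adjusted over the list alone are given beside it, and no list call at the preset passed with an estimated correlation. The lists were antimicrobial peptides, Bomanins and other Toll-induced peptides, immune recognition and NF-kB signalling, Turandot and JAK-STAT genes, circadian clock, sleep regulators, neuropeptides, activity-regulated genes, synapse and neuronal core, glia, phototransduction, odorant binding proteins, heat shock proteins, unfolded protein response, glutathione S-transferases, cytochrome P450, antioxidant enzymes, nuclear-encoded oxidative phosphorylation, mitochondrial-genome genes, cytosolic ribosomal proteins, proteasome, glycolysis, insulin and FOXO, lipid storage and turnover, autophagy, digestive enzymes, muscle, fat body, hemocyte, testis, male accessory gland, yolk and eggshell, and cuticular proteins. Of the list members 3 were not found in the table.

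The genes named follow a rule: in each comparison, among changed genes with a mean of at least 1 CPM in the tissue, the 8 rising and the 8 falling genes with the largest change whose symbol is not a bare CG or CR number, and 2 in each direction whatever the symbol; where none passed, the 3 with the smallest p; from each list that was called or had at least 3 changed members, up to 4 with the smallest adjusted p; for tissue differences, the 5 with the smallest adjusted p; and per library a set of marker genes for carry-over between tissues. Groups, lists, tests, the naming rule and the alternatives to be tried were chosen before the data were examined. Symbols are those of the count table (IM23 is now BomBc1, IM1 and IM2 are BomS1 and BomS2, ImpL3 is Ldh, Cg25C is Col4a1), and coordinates are those of the BDGP6 assembly, which is dm6, from a current Ensembl annotation that holds 17253 of the gene IDs. Counting was treated as unstranded, so a gene can share reads with one that overlaps it, and the share of its exonic sequence is given where it matters.

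The alternatives were RLE scaling, no filter on low counts, a filter of at least 5 CPM in at least 5 libraries, a minimum of 2-fold, DESeq2 1.42.0, limma voom with quality weights, only the compared groups in the fit, the replicate number as a block, and leaving out each library in turn; for lists also an estimated correlation and the rotation test fry. Leaving out aged NSF bodies 1 and 2 together was added after their marker genes had been seen. List tests of tissue differences were not rerun without single libraries. The other splits of the libraries, 100 per comparison and 50 per interaction, were drawn with a fixed seed. Permutations, scores and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The tests were tested on simulated data: changes of 1 log2 put into the counts were called in 57.0 to 63.9% of genes in heads and 32.3 to 44.9% in bodies, changes of 2 log2 in 90.8 to 98.0% and 85.7 to 91.8%, and 2.50 to 7.59% of calls were false. A raised list was called in both tissues and 0 others. False list calls from correlated genes were not tested.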

Results

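Poly(A) RNA was sequenced from the heads and from the bodies of individual male flies of the Cantonized w1118 strain, a white-eyed laboratory line in a Canton-S background. The flies were taken after a sleep assay at 5 days (young) or 25 days of age (aged). Young flies slept normally, and aged flies fell into those that still did (aged NSF) and those whose sleep had become fragmented (aged SF). Each of the 6 groups held 5 libraries, 30 in total.

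Reads counted on genes, in replicate order, were 2194571, 3597530, 1685034, 2364465 and 2676541 in young heads, 2449151, 2761317, 3099585, 2682764 and 1712101 in aged NSF heads and 2369839, 2299598, 2250040, 2535467 and 2137220 in aged SF heads. Bodies had 6063791, 6068426, 5266092, 3054186 and 4297885 reads in the young, 3615993, 2458538, 4527543, 4207557 and 4212745 in the aged NSF and 8060238, 3360721, 4363482, 5233673 and 2996035 in the aged SF group. With a floor of 3 counts, a gene without reads can still stand at 0.834 to 1.78 CPM, counts scaled to equal library totals, in a head and 0.372 to 1.22 CPM in a body. Where several values name several libraries, each was left out singly, in that order. Floors and counting intervals cover counting error only. Gene levels are means ± SD over 5 flies in CPM scaled with TMM factors. Values beside gene symbols without a unit are log2 fold changes, with a standard error where ± follows.

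What age changes in the head of a fly that still sleeps normally is the first comparison, and immune genes lead its increases. SPH93 (FBgn0032638, chromosome 2L, 17454263 to 17455923, minus strand), which encodes a serine protease homologue, rose from 0.0820 ± 0.183 to 113 ± 13.9 CPM (SD, n = 5), with a log2 fold change of 9.69 ± 0.45 and an edgeR adjusted p of 3.3e-12. All young heads together held 1 read of it, so that the ratio of counts was 1300 with a 95% counting interval of 233 to 51500. The antifungal peptide gene Drs (FBgn0010381) rose from 38.2 ± 22.9 to 4159 ± 3306 CPM and the immune-induced peptide gene edin (FBgn0052185) from 1.73 ± 3.18 to 215 ± 156 CPM. Antimicrobial peptide genes rose in 13 of 14 cases and fell in none, and 14 rose adjusted over the list alone (median 4.54, camera adjusted p = 1.36e-12, adjusted p = 0.217 with an estimated correlation). AttD (7.51), CecB (7.08) and CecC (4.84) were among them. 12 of 18 Bomanin and other Toll-induced peptide genes rose and none fell, and 14 rose and 1 fell adjusted over the list alone (median 2.42, camera adjusted p = 3.1e-07, adjusted p = 0.385 with an estimated correlation). IM23 (6.82) and IM1 (4.0) led that list.

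Immune signalling genes moved with the peptides. Genes of immune recognition and NF-kB signalling rose in 13 and fell in 1 of 28 cases, and 16 rose and 1 fell adjusted over the list alone (median 0.62, camera adjusted p = 5.41e-07, adjusted p = 0.198 with an estimated correlation). They include the peptidoglycan receptor gene PGRP-SA (2.95), the Imd feedback inhibitor pirk (2.26) and the Toll transcription factor dl (0.98). Turandot and JAK-STAT genes rose in 5 and fell in 4 of 11 cases, and 5 rose and 4 fell adjusted over the list alone (median -0.02, camera adjusted p = 0.8, mean -0.10, test pointing up). The cytokine gene upd3 (3.51) and the feedback gene Socs36E (1.46) rose, and the transcription factor gene Stat92E (-1.08) fell. 3 of 10 hemocyte markers fell and none rose, and 3 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.289, mean -0.22, test pointing down). Pxn, vkg and Cg25C, genes of the extracellular matrix, were the hemocyte markers that fell.

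Energy metabolism moved the other way. Nuclear genes of oxidative phosphorylation fell in 56 of 61 cases and rose in none, and 60 fell adjusted over the list alone (median -0.75, camera adjusted p = 1.51e-24, adjusted p = 0.198 with an estimated correlation). ATPsyn-gamma, a subunit of the ATP synthase, fell from 599.6 ± 138 to 268 ± 30.4 CPM (SD, n = 5). Mitochondrial-genome genes fell in 6 of 12 cases and rose in none, and 6 fell adjusted over the list alone (median -0.42, camera adjusted p = 0.00936, adjusted p = 0.485 with an estimated correlation). 2 of 12 glycolysis genes rose and 8 fell, and 2 rose and 8 fell adjusted over the list alone (median -0.41, camera adjusted p = 0.0277, adjusted p = 0.485 with an estimated correlation). Gapdh1 (-0.83) and PyK (-0.74) fell while the lactate dehydrogenase gene ImpL3 (3.12) rose, and without aged NSF head 5 the list's adjusted p was 0.0542. Muscle genes fell in 11 of 23 cases and rose in none, and 15 fell adjusted over the list alone (median -0.48, camera adjusted p = 2.24e-06, adjusted p = 0.217 with an estimated correlation). The myosin heavy chain gene Mhc (-1.34) and the light chain gene Mlc2 (-1.18) were among those that fell.

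Neuronal and sensory genes were lower as well. Synaptic genes fell in 11 of 25 cases and rose in none, and 12 fell adjusted over the list alone (median -0.33, camera adjusted p = 0.00144, adjusted p = 0.485 with an estimated correlation). Their median moved to -0.15 and -0.21 without young heads 1 and 5. Gad1, which makes the transmitter GABA, fell by 1.05 on the log2 scale, and the vesicle fusion genes comt (-1.03) and cpx (-0.90) fell too. 2 of 27 phototransduction genes rose and 13 fell, and 2 rose and 15 fell adjusted over the list alone (median -0.42, camera adjusted p = 0.000159, adjusted p = 0.385 with an estimated correlation). CdsA (-0.95) and the G protein subunit gene Gbeta76C (-0.95) stand for them. Odorant binding protein genes rose in 1 and fell in 6 of 25 cases, and 1 rose and 7 fell adjusted over the list alone (median -0.94, camera adjusted p = 0.000888, adjusted p = 0.397 with an estimated correlation). Glial genes rose in 3 and fell in 7 of 15 cases, and 3 rose and 7 fell adjusted over the list alone (median -0.32, camera adjusted p = 0.0746), with an adjusted p of 0.0409 without aged NSF head 3. The glutamate transporter gene Eaat1 (-1.64) fell and the amine-conjugating enzyme gene e (2.44) rose.

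Neuropeptide and behavioural genes moved in both directions. 6 of 32 neuropeptide genes rose and 6 fell, and 8 rose and 6 fell adjusted over the list alone (median 0.13, camera adjusted p = 0.796, mean -0.14, test pointing up). Hug (FBgn0028374, chromosome 3R, 12526188 to 12529076, plus strand), the precursor of pyrokinins, rose from 94.3 ± 12.9 to 217 ± 30.6 CPM (SD, n = 5), while SIFa (-1.40) and Nplp3 (-3.63) fell. Sleep regulators rose in 4 and fell in 4 of 33 cases, and 4 rose and 4 fell adjusted over the list alone (median -0.06, camera adjusted p = 0.643). The dopamine synthesis gene ple (2.05) rose and the scaffold gene homer (-0.73) fell. Clock genes rose in 3 and fell in 2 of 13 cases, and 4 rose and 2 fell adjusted over the list alone (median 0.06, camera adjusted p = 0.442). The clock genes vri (1.43), per (0.98) and tim (0.90) rose and the blue-light receptor gene cry (-1.0) fell. 1 of 8 activity-regulated genes rose and 2 fell, and 1 rose and 3 fell adjusted over the list alone (median -0.33, camera adjusted p = 0.318). The labels give 1 batch date for all flies and no time of day.

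Storage and nutrient genes were lower in part. Fat body genes fell in 4 of 12 cases and rose in none, and 2 rose and 8 fell adjusted over the list alone (median -1.36, camera adjusted p = 0.00677, adjusted p = 0.473 with an estimated correlation). The storage protein gene Lsp1beta (-4.66 ± 0.78), the insulin-responsive glucosidase gene tobi (-4.36 ± 0.93) and Lsp2 (-3.99) fell, and Lsp2 shares 84.6% of its exonic sequence with an overlapping gene. Lipid genes rose in 4 and fell in 7 of 17 cases, and 5 rose and 11 fell adjusted over the list alone (median -0.42, camera adjusted p = 0.0746). The lipase gene bmm (1.21) rose and the acetyl-CoA carboxylase gene ACC (-1.34) fell, and the list passed without young head 2 (0.0369) or aged NSF head 4 (0.0257). 2 of 21 insulin and FOXO genes rose and 4 fell, and 3 rose and 4 fell adjusted over the list alone (median 0.09, camera adjusted p = 0.8, mean -0.04, test pointing up). The receptor gene InR (1.85) rose and the insulin-like peptide genes Ilp3 (-2.22) and Ilp5 (-1.17) fell. Digestive enzyme genes rose in 2 and fell in 1 of 6 cases, and 2 rose and 1 fell adjusted over the list alone (median 0.15, camera adjusted p = 0.289). The near-identical amylase genes Amy-p (4.78) and Amy-d (3.37) rose, and reads can be split between such copies.

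Stress and turnover genes gave mixed results. Proteasome genes rose in 4 of 31 cases and fell in none, and 4 rose adjusted over the list alone (median 0.27, camera adjusted p = 0.00132, adjusted p = 0.485 with an estimated correlation). 6 of 17 heat shock genes rose and 3 fell, and 9 rose and 3 fell adjusted over the list alone (median 0.57, camera adjusted p = 0.064), and the list passed without aged NSF head 4 (0.0452), aged SF head 2 (0.0371) or aged SF head 5 (0.034). Unfolded protein response genes rose in 4 of 16 cases and fell in none, and 4 rose adjusted over the list alone (median 0.28, camera adjusted p = 0.0578). That list passed without young head 2 (0.0251), aged NSF head 3 (0.0265) or 5 (0.0414), or aged SF head 2 (0.0461). Cytochrome P450 genes rose in 8 and fell in 17 of 66 cases, and 9 rose and 18 fell adjusted over the list alone (median -0.23, camera adjusted p = 0.0311, adjusted p = 0.485 with an estimated correlation). Cyp6g1 (-1.13) fell, and without young head 4 the P450 list had an adjusted p of 0.0665, and without young head 2 a median of -0.36. 5 of 30 glutathione S-transferase genes rose and 4 fell, and 5 rose and 4 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.796). Antioxidant enzyme genes rose in 4 and fell in 2 of 20 cases, and 4 rose and 2 fell adjusted over the list alone (median 0.10, camera adjusted p = 0.981).

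The machinery of translation changed little in heads. Ribosomal protein genes rose in 3 and fell in 1 of 81 cases, and 1 rose adjusted over the list alone (median 0.04, camera adjusted p = 0.599), with an adjusted p of 0.0188 without young head 4. 1 of 20 autophagy genes rose and none fell, and 1 rose adjusted over the list alone (median -0.15, camera adjusted p = 0.657). Cuticular protein genes rose in 7 and fell in 5 of 19 cases, and 7 rose and 5 fell adjusted over the list alone (median 0.15, camera adjusted p = 0.981, mean 0.73, test pointing down). Cpr49Ac, at 0 in all young heads, was at least 9.25-fold higher in aged NSF heads against the floor. Testis, male accessory gland and yolk genes had 3, 2 and 3 tested members in heads, too few for a list test, and 0 changed, over all genes or adjusted over the list alone.

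In all, 2075 of 9088 genes changed between aged NSF and young heads, 1032 higher and 1043 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was found for 883 of them. The groups did not overlap for 1448 genes, where chance would give 0.79% of genes. CG9676 went from 659 ± 432 to 0.188 ± 0.273 CPM (SD, n = 5), with 2 reads left in the aged heads and a ratio of counts, young over aged, of 4770 (95% counting interval 1320 to 39400).

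**Figure D1:**
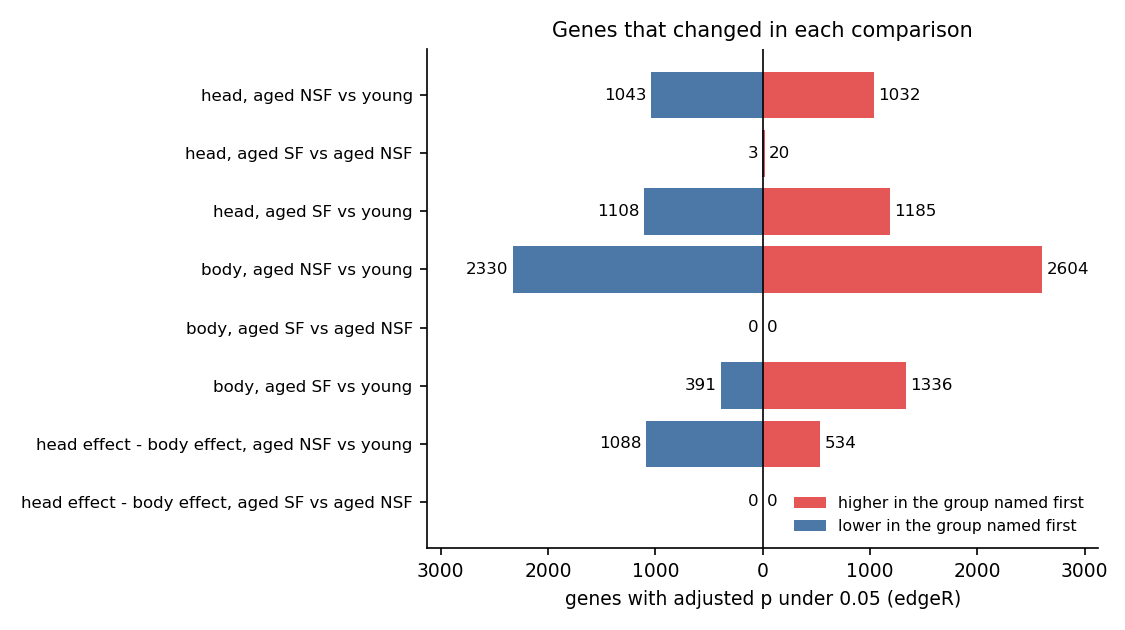
Number of genes changed at an edgeR adjusted p under 0.05 in each comparison, higher and lower shown apart, on an axis that starts at 0. Aged NSF against young gave 2075 in heads and 4934 in bodies, and aged SF against aged NSF 23 and 0.

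Fragmented and normal sleepers of equal age are compared next, in the head. SPH93, which rose with age, was higher again, from 113 ± 13.9 to 318 ± 120.1 CPM (SD, n = 5, 1.5 ± 0.21, edgeR adjusted p = 0.0017). Hml (FBgn0029167, chromosome 3L, 13846054 to 13860001, plus strand), which encodes the clotting protein hemolectin of hemocytes, fell from 43.9 ± 13.3 to 13.8 ± 5.56 CPM (-1.67 ± 0.28, adjusted p = 0.00346). The neuropeptide gene Hug fell from 217 ± 30.6 to 135 ± 6.80 CPM (-0.69 ± 0.13, adjusted p = 0.0125), opposite to its rise with age in normal sleepers. Drsl4 (FBgn0052282, chromosome 3L, 3315620 to 3315942, plus strand), a Drosomycin-like peptide gene, rose from 6.63 ± 4.01 to 78.5 ± 39.8 CPM (3.52 ± 0.53, adjusted p = 0.0125), and CG11370 from 11.7 ± 5.35 to 105 ± 71.1 CPM.

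Also higher were the JAK-STAT transcription factor gene Stat92E (0.71), the odorant binding protein genes Obp56d (0.67) and Obp57a (1.13) and the glial apolipoprotein D homologue GLaz (1.08). Cyp4e3 (1.05), the pigmentation gene yellow-e (2.11) and the cuticle gene Cpr49Ae (1.18) rose, and the mitochondrial complex I gene mt:ND4L (-1.94) fell. All aged NSF heads were below all young heads in Stat92E, GLaz, Obp57a and Cpr49Ae, and the aged SF means lay between those groups. Both comparisons share the aged NSF heads. Their deviation alone would give Hug and these genes opposite signs. All aged SF exceeded all young heads in Obp56d and Cyp4e3. With each head left out in turn, SPH93 and Hml passed in 15 of 15 fits, Drsl4 and CG11370 in 13 and Hug and Obp56d in 12. Cpr49Ae passed in 9, GLaz and Stat92E in 7, and Cyp4e3, Obp57a, mt:ND4L and yellow-e in 5. Drsl4 and CG11370 were lost without aged NSF head 4 (adjusted p = 0.0516 for both) or 5 (0.0541 and 0.0531). Hug was lost without aged SF head 1 (0.0515), 3 (0.0516) or 4 (0.064). Obp56d was lost without aged NSF head 4 (0.0658) or aged SF head 3 (0.0994) or 4 (0.055).

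**Figure D2:**
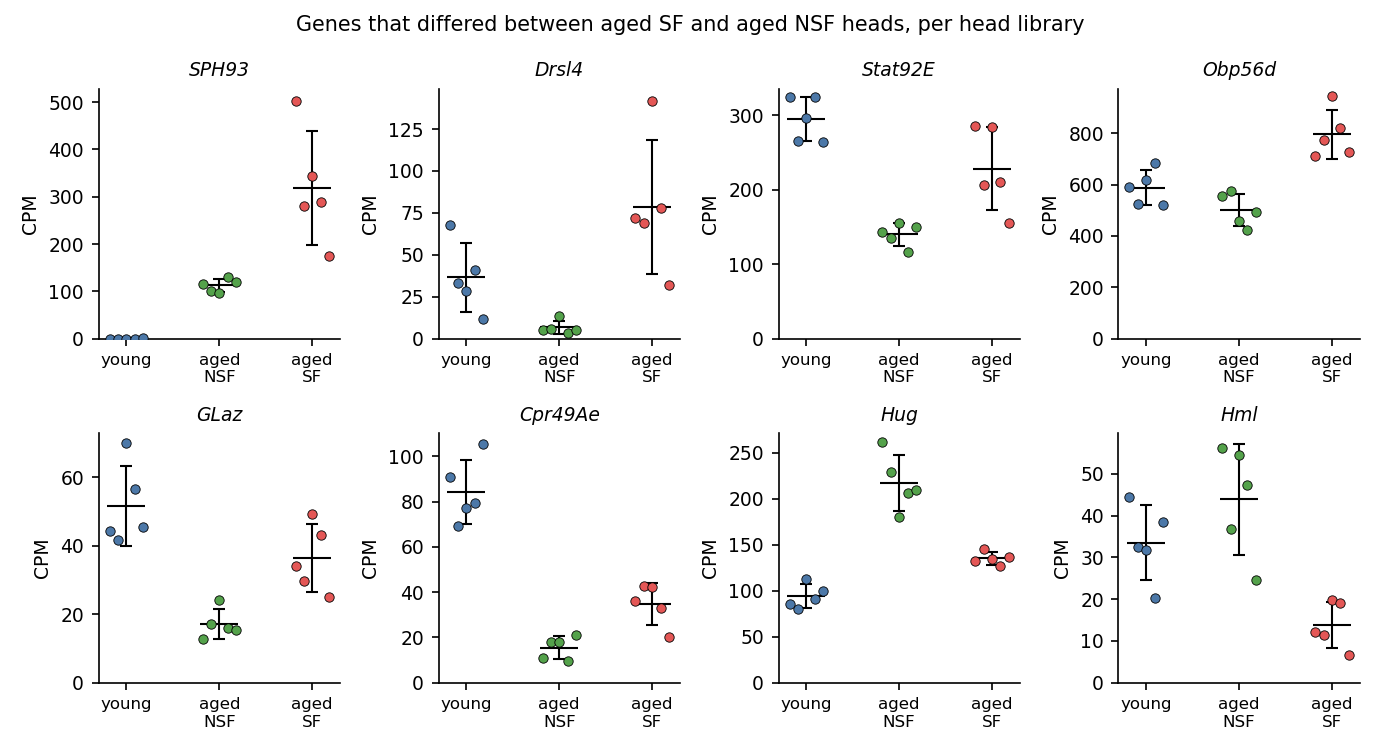
CPM of 8 genes that differed between aged SF and aged NSF heads, in young, aged NSF and aged SF heads on axes that start at 0, with points for single flies, a horizontal bar for the mean and an error bar for the SD (n = 5 per group). In aged SF against aged NSF heads SPH93 (1.5) was higher and Hml (-1.67) and Hug (-0.69) were lower.

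Turandot, heat shock, fat body, odorant binding, glial and glutathione S-transferase genes were higher in fragmented sleepers as lists. Turandot and JAK-STAT genes rose in 1 of 11 cases and fell in none, and 4 rose adjusted over the list alone (median 0.29, camera adjusted p = 1.94e-05, adjusted p = 0.269 with an estimated correlation). The median moved to 0.49 and 0.50 without young heads 1 and 4, 0.54 and 0.91 without aged NSF heads 1 and 5, and 0.45 and 0.66 without aged SF heads 2 and 5. Stat92E is the member that passed over all genes. Heat shock genes had 0 of 17 members past the test over all genes, and 7 rose adjusted over the list alone (median 0.49, camera adjusted p = 9.5e-05, adjusted p = 0.269 with an estimated correlation). Of 12 fat body genes, 0 passed over all genes and 3 rose adjusted over the list alone (median 0.58, camera adjusted p = 0.000139, adjusted p = 0.269 with an estimated correlation). Odorant binding protein genes rose in 2 of 25 cases and fell in none, and 3 rose and 1 fell adjusted over the list alone (median 0.28, camera adjusted p = 0.0317, adjusted p = 0.582 with an estimated correlation). That call moved to an adjusted p of 0.106 and 0.0773 without aged NSF heads 4 and 5, and 0.259 and 0.0549 without aged SF heads 3 and 4. The odorant binding median moved to 0.51, 0.62, 0.13 and 0.16 without aged NSF heads 1, 2, 4 and 5, and 0.50, 0.54, -0.05 and 0.44 without aged SF heads 1, 2, 3 and 5. Glial genes had 0 of 15 members past the test over all genes, and 0 changed adjusted over the list alone (median 0.20, camera adjusted p = 0.0405, adjusted p = 0.582 with an estimated correlation). Their adjusted p moved to 0.296 and 0.0676 without aged NSF heads 4 and 5, and 0.0864, 0.0538 and 0.0518 without aged SF heads 1, 3 and 5, and the median to 0.12 without aged NSF head 4. Of 30 glutathione S-transferase genes, 0 passed over all genes and 0 changed adjusted over the list alone (median 0.16, camera adjusted p = 0.0317, adjusted p = 0.575 with an estimated correlation). For the transferases it moved to 0.0875, 0.0544 and 0.0773 without aged NSF heads 1, 4 and 5, and 0.0705 and 0.0514 without aged SF heads 3 and 5, and the median to 0.24 and 0.24 without aged NSF heads 1 and 3, and 0.27, 0.25 and 0.10 without aged SF heads 1, 2 and 4.

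Antimicrobial peptide, hemocyte, muscle and mitochondrial genes were lower in fragmented sleepers as lists. None of 14 antimicrobial peptide genes passed over all genes, and 0 changed adjusted over the list alone (median -0.66, camera adjusted p = 0.00694, adjusted p = 0.582 with an estimated correlation). The call was lost without aged NSF head 5 (0.0773) or aged SF head 1 (0.116), and the median moved to -1.23 without aged SF head 2. The other effector list pointed up. Bomanin and other Toll-induced peptide genes had 0 of 18 members past the test over all genes, and 0 changed adjusted over the list alone (median 0.18, camera adjusted p = 0.054). It passed, upward, without aged NSF head 4 (0.00128) or 5 (0.00199) or aged SF head 5 (0.00628). Hemocyte markers fell in 1 of 10 cases and rose in none, and 3 fell adjusted over the list alone (median -0.23, camera adjusted p = 0.00501, adjusted p = 0.269 with an estimated correlation), with an adjusted p of 0.0518 without aged SF head 5. None of 23 muscle genes passed over all genes, and 3 fell adjusted over the list alone (median -0.18, camera adjusted p = 0.00509, adjusted p = 0.562 with an estimated correlation), with an adjusted p of 0.0676 without aged SF head 4. 1 of 12 mitochondrial-genome genes fell and none rose, and 3 fell adjusted over the list alone (median -0.37, camera adjusted p = 0.00694, adjusted p = 0.582 with an estimated correlation). That call was lost without aged NSF head 5 (0.085) or aged SF head 3 (0.0538), and the median was -0.19 without aged NSF head 5. Of 31 proteasome genes, 0 passed over all genes and 0 changed adjusted over the list alone (median -0.12, camera adjusted p = 0.0197, adjusted p = 0.582 with an estimated correlation). For the proteasome the value was 0.0969 and 0.106 without aged NSF heads 3 and 4, and 0.071 without aged SF head 1.

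The lists closest to behaviour did not pass. None of 33 sleep regulators, 13 clock genes, 25 synaptic genes and 27 phototransduction genes passed over all genes, and of these 1 clock gene rose adjusted over the list alone. The camera adjusted p was 0.382, 0.286, 0.286 and 0.716, and the phototransduction list had a median of -0.01 and a mean of 0.01.

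Over all 9088 genes tested in heads, 23 changed, 20 higher and 3 lower in fragmented sleepers (edgeR, adjusted p under 0.05), and 848 had an unadjusted p under 0.05. The groups did not overlap for 182 genes, where chance gives 0.79%. The count of changed genes moved to 9 without aged SF head 3 or 4, 10 without aged NSF head 4 or aged SF head 1, and 11 without aged NSF head 5. It was 15 without aged NSF head 2 or aged SF head 2 and 61 without aged SF head 5. DESeq2 gave 86 genes, and the list deposited by the authors has 101, which hold all 23.

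Fragmented sleepers against young flies show age and fragmented sleep together in the head. SPH93 reached 318 ± 120.1 CPM (SD, n = 5), a ratio of counts of 3760 to young heads (95% counting interval 674 to 148000). PGRP-SC2, which encodes an amidase that degrades peptidoglycan, rose from 6.33 ± 10.5 to 565 ± 419.5 CPM (6.42 ± 0.92, edgeR adjusted p = 0.000222). Antimicrobial peptide genes rose in 10 of 14 cases and fell in none, and 13 rose adjusted over the list alone (median 3.59, camera adjusted p = 1.13e-09, adjusted p = 0.256 with an estimated correlation). That median was 5.61 without young head 5. Tep4 (1.28), an opsonin-like gene, and upd3 (3.70) rose.

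Chaperone genes were higher than in young heads. 11 of 17 heat shock genes rose and 3 fell, and 11 rose and 3 fell adjusted over the list alone (median 0.92, camera adjusted p = 0.00068, adjusted p = 0.271 with an estimated correlation). Hsp83 (0.79) and Hsp70Bc (3.26) rose, the latter being 1 of several near-identical copies. The disulfide isomerase gene CaBP1 (1.24) of the unfolded protein response rose too.

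Energy and muscle genes were lower than in young heads. Nuclear genes of oxidative phosphorylation fell in 55 of 61 cases and rose in none, and 58 fell adjusted over the list alone (median -0.87, camera adjusted p = 2.04e-25, adjusted p = 0.104 with an estimated correlation). Muscle genes fell in 15 of 23 cases and rose in none, and 15 fell adjusted over the list alone (median -0.55, camera adjusted p = 6.75e-09, adjusted p = 0.104 with an estimated correlation). The flight muscle actin gene Act88F fell from 29.1 ± 12.4 to 2.94 ± 1.92 CPM and the insulin-like peptide gene Ilp3 from 18.8 ± 7.41 to 2.43 ± 2.25 CPM (SD, n = 5). The ecdysteroid hydroxylase gene Cyp18a1 (-2.65) fell as well. Of 9088 genes 2293 changed, 1185 higher and 1108 lower, 913 of them by at least 2-fold. Groups did not overlap for 1657 genes, against a chance share of 0.79%.

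**Figure D3:**
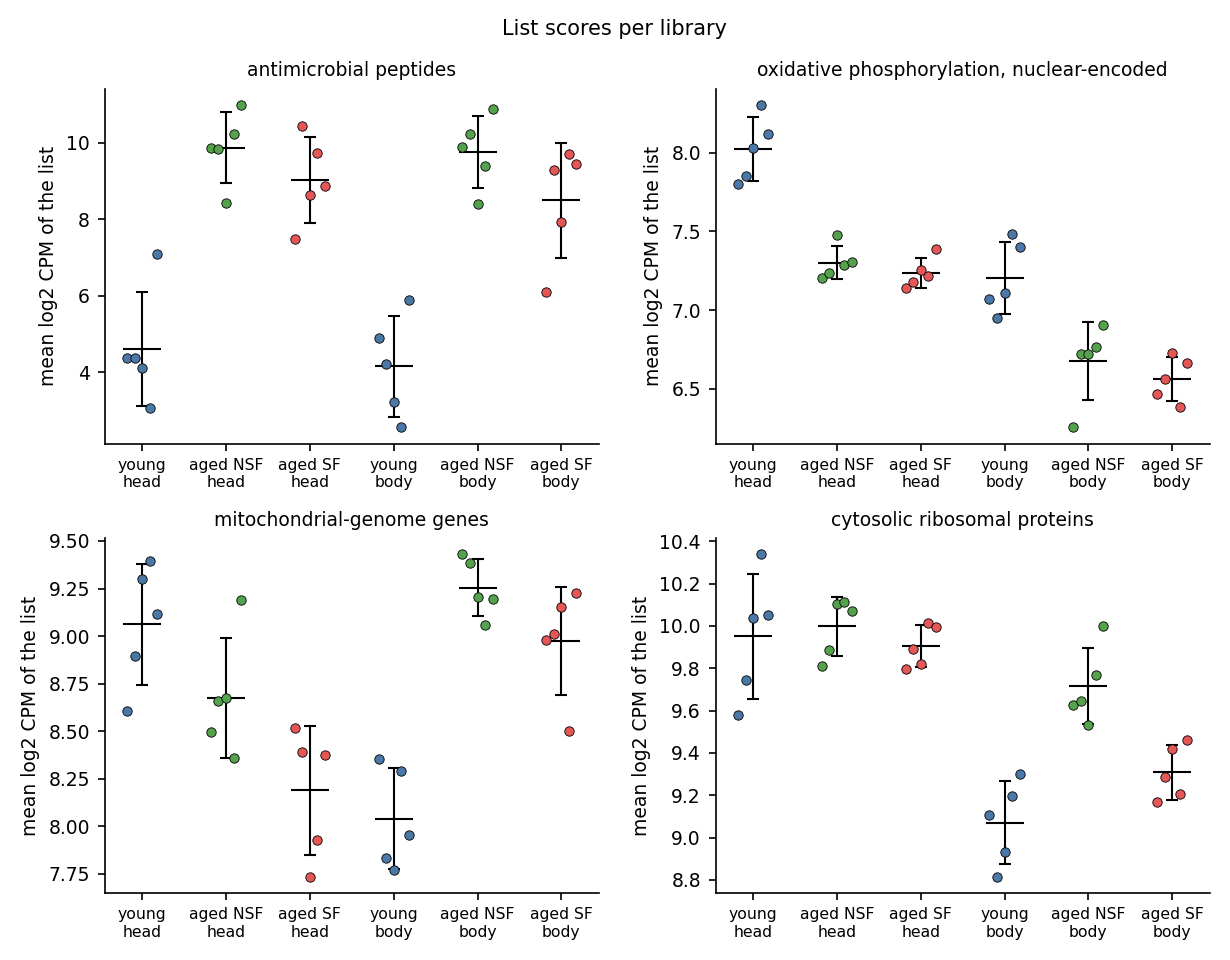
Mean log2 CPM of 4 gene lists in each library, by group, in heads and bodies, where points are single flies, the horizontal bar is the mean and the error bar the SD (n = 5). The antimicrobial peptide score was 4.61 ± 1.49 in young and 9.87 ± 0.93 in aged NSF heads, and the oxidative phosphorylation score 8.02 ± 0.20 and 7.30 ± 0.11.

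In the body, aged flies that sleep normally are set against young flies, and immune genes again lead the increases. The peptide gene edin (FBgn0052185, chromosome 3L, 17494880 to 17495300, plus strand) rose from 0.144 ± 0.322 to 98.6 ± 98.0 CPM (SD, n = 5, edgeR adjusted p = 0.000484). From 3 reads in all young bodies the ratio of counts was 790 (95% counting interval 270 to 3830). 14 of 14 antimicrobial peptide genes rose and none fell, and 14 rose adjusted over the list alone (median 5.94, camera adjusted p = 9.92e-10, adjusted p = 0.399 with an estimated correlation). Drs rose from 23.4 ± 9.12 to 2980.2 ± 2088 CPM. Bomanin and other Toll-induced peptide genes rose in 18 of 20 cases and fell in none, and 18 rose adjusted over the list alone (median 3.51, camera adjusted p = 2.42e-13, adjusted p = 0.22 with an estimated correlation). Immune recognition genes rose in 23 of 29 cases and fell in none, and 24 rose and 1 fell adjusted over the list alone (median 1.24, camera adjusted p = 7.82e-09, adjusted p = 0.22 with an estimated correlation). IM2 (4.0) and the receptor gene PGRP-LC (1.24) are examples. 6 of 13 Turandot and JAK-STAT genes rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone (median 0.99, camera adjusted p = 0.102). The opsonin-like genes Tep2 (2.44) and Tep4 (3.22) rose.

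Translation, mitochondrial-genome and protein quality genes were higher in aged NSF bodies, and nuclear respiratory genes lower. Ribosomal protein genes rose in 78 and fell in 2 of 87 cases, and 80 rose and 2 fell adjusted over the list alone (median 0.78, camera adjusted p = 1.64e-20, adjusted p = 0.399 with an estimated correlation). RpS21 (1.15) and RpS3A (0.91) rose. Mitochondrial-genome genes rose in 9 of 12 cases and fell in none, and 11 rose adjusted over the list alone (median 0.84, camera adjusted p = 5.05e-06, adjusted p = 0.399 with an estimated correlation). The complex I gene mt:ND2 (3.24) and mt:Cyt-b (0.76) rose. 20 of 81 nuclear genes of oxidative phosphorylation fell and none rose, and 12 fell adjusted over the list alone (median -0.29, camera adjusted p = 3.43e-05, adjusted p = 0.56 with an estimated correlation). Unfolded protein response genes rose in 9 and fell in 1 of 16 cases, and 11 rose and 1 fell adjusted over the list alone (median 0.49, camera adjusted p = 0.0027, adjusted p = 0.399 with an estimated correlation). The autophagy gene Atg8a (0.95), which coats autophagosomes, rose.

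Insulin receptor and proteasome genes were higher too. The insulin receptor gene InR rose from 22.4 ± 6.5 to 151 ± 73.0 CPM (SD, n = 5). Proteasome genes rose in 9 of 32 cases and fell in none, and 9 rose adjusted over the list alone (median 0.22, camera adjusted p = 0.0423, adjusted p = 0.659 with an estimated correlation). That call was lost under RLE scaling (adjusted p = 0.0688), without young body 1 (0.102) or 2 (0.0755), and without aged NSF body 3 (0.0543), 4 (0.0589) or 5 (0.0561), and the median was 0.33 without aged NSF bodies 1 and 2. The ion transport peptide gene ITP (1.31) rose and Nplp3 (-4.79) fell. 7 of 13 clock genes rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (median 0.53, camera adjusted p = 0.0553), and the list passed without young body 1 (0.033) or aged NSF body 5 (0.0333). The clock genes vri (1.11) and per (1.41) rose.

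Muscle and gut genes were lower. Muscle genes rose in 2 and fell in 17 of 25 cases, and 2 rose and 20 fell adjusted over the list alone (median -0.72, camera adjusted p = 3.78e-06, adjusted p = 0.399 with an estimated correlation). The actin gene Act79B (-2.28) and the troponin T gene up (-0.85) fell. Digestive enzyme genes rose in 4 and fell in 18 of 39 cases, and 4 rose and 19 fell adjusted over the list alone (median -0.84, camera adjusted p = 0.00321, adjusted p = 0.599 with an estimated correlation). The median was -1.29 without aged NSF body 1, and -1.43 without aged NSF bodies 1 and 2. The proteases Jon65Aii (-5.21) and epsilonTry (-2.81) fell. The sterol-binding gene Npc2d was at 0 in all aged NSF bodies, at least 14.2-fold lower than its 12.2 ± 6.72 CPM (SD, n = 5) in young bodies against a floor of 3 counts per library, and with it at that bound the list's median is still -0.84. The prophenoloxidase gene PPO2, a melanisation enzyme of crystal cells, fell from 8.66 ± 2.88 to 0.582 ± 0.677 CPM.

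Reproductive genes of the aged NSF bodies are given with the libraries that stood apart in them. 21 of 32 testis genes fell and none rose, and 25 fell adjusted over the list alone (median -1.11, camera adjusted p = 1.49e-07, adjusted p = 0.547 with an estimated correlation). Aged NSF body 1 held 52.0 CPM of library total of the sperm tubulin gene betaTub85D, against 396 to 552 in the other aged NSF bodies. Without aged NSF bodies 1 and 2 the testis median was -0.88 (adjusted p = 1.83e-07). Male accessory gland genes rose in 1 and fell in 3 of 26 cases, and 1 rose and 2 fell adjusted over the list alone (median -0.33, camera adjusted p = 0.0532). That list passed without aged NSF bodies 1 and 2 (-1.01, adjusted p = 0.00011), without body 1 (-0.66, 0.00672) or without body 2 (-0.39, 0.0175). It passed as well without young body 1 (0.033), 2 (0.0498) or 3 (0.029) or aged SF body 2 (0.0489), 3 (0.0484) or 4 (0.0314). Of 4 yolk and eggshell genes Yp1, Yp2 and Yp3 rose, and 3 rose adjusted over the list alone. Aged NSF body 2 stood at 288 CPM of library total of Yp1 and the other aged NSF bodies at 11.9 to 28.2. Without bodies 1 and 2 the calls of Yp2 and Yp3 were lost, and Yp1 shares 54.3% of its exonic sequence with an overlapping gene. Phototransduction genes rose in 9 and fell in 1 of 19 cases, and 9 rose and 1 fell adjusted over the list alone (median 0.65, camera adjusted p = 0.108), with a median of 0.20 and an adjusted p of 0.275 without aged NSF bodies 1 and 2. The rhodopsin gene ninaE stood at 324 CPM of library total in aged NSF body 2 and at 4.42 to 11.9 in the others.

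Over all 12009 genes tested in bodies 4934 changed, 2604 higher and 2330 lower, 2610 of them by at least 2-fold (edgeR, adjusted p under 0.05). Groups did not overlap for 3222 genes, against a chance share of 0.79%. The balance turned to 2432 higher and 2648 lower with RLE scaling, 2652 and 3070 with DESeq2, 931 and 1679 at 2-fold and 2563 and 2678 without aged NSF body 1.

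**Figure D4:**
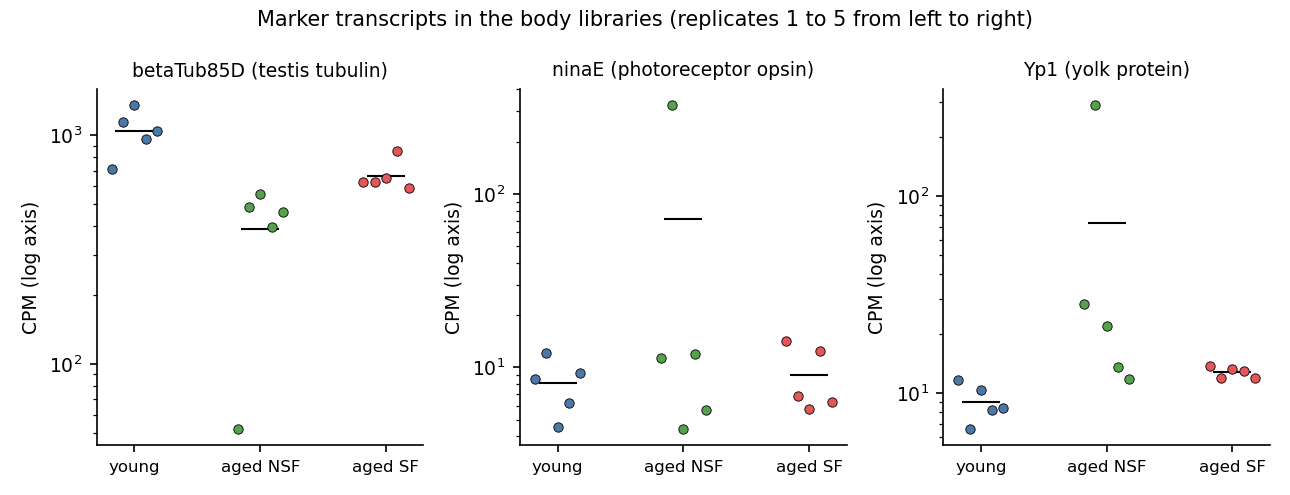
CPM of library total of marker genes of other tissues in each of the 15 body libraries, on a log axis, with points for single flies and a line for the arithmetic mean of the group. Aged NSF body 1 stands low in betaTub85D, at 52.0 CPM, and aged NSF body 2 stands high in ninaE, at 324 CPM, and Yp1, at 288 CPM.

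Between aged SF and NSF bodies 0 genes passed by edgeR and 604 by DESeq2. Families differed at the preset correlation only. Ribosomal protein genes, which rose with age in normal sleepers, were lower in SF bodies, with 5 of 87 above 0. Of the ribosomal genes 0 passed over all genes and 79 fell adjusted over the list alone. Their median was -0.49 (camera adjusted p = 4.03e-33, adjusted p = 0.515 with an estimated correlation). Without aged NSF bodies 1 and 2 their median was -0.51 (adjusted p = 2.18e-27). Of 81 nuclear genes of oxidative phosphorylation, 0 passed over all genes and 2 rose and 36 fell adjusted over the list alone (median -0.41, camera adjusted p = 1.4e-09, adjusted p = 0.515 with an estimated correlation). None of 32 proteasome genes passed over all genes, and 7 fell adjusted over the list alone (median -0.22, camera adjusted p = 1.71e-07, adjusted p = 0.515 with an estimated correlation), with a median of -0.34 without aged NSF bodies 1 and 2. Glycolysis genes had 0 of 12 members past the test over all genes, and 6 fell adjusted over the list alone (median -0.37, camera adjusted p = 3.48e-06, adjusted p = 0.515 with an estimated correlation). Of 25 muscle genes, 0 passed over all genes and 7 fell adjusted over the list alone (median -0.38, camera adjusted p = 3.03e-07, adjusted p = 0.515 with an estimated correlation), with a median of -0.17 without aged NSF bodies 1 and 2.

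Immune effector genes were lower and gut enzyme genes higher in SF bodies as lists, at the preset correlation. None of 14 antimicrobial peptide genes passed over all genes, and 0 changed adjusted over the list alone (median -0.90, camera adjusted p = 0.000516, adjusted p = 0.515 with an estimated correlation). The median moved to -0.57 without aged NSF body 5 and -1.42 without aged SF body 4. Bomanin and other Toll-induced peptide genes had 0 of 20 members past the test over all genes, and 1 fell adjusted over the list alone (median -0.56, camera adjusted p = 0.00105, adjusted p = 0.515 with an estimated correlation). Of 29 immune recognition genes, 0 passed over all genes and 1 rose adjusted over the list alone (median -0.26, camera adjusted p = 0.0226, adjusted p = 0.515 with an estimated correlation). The recognition call moved to 0.173 without aged NSF bodies 1 and 2, and was lost without aged NSF body 1 (0.0703) or 5 (0.0653) or aged SF body 1 (0.107) or 3 (0.0791, median -0.15). None of 39 digestive enzyme genes passed over all genes, and 10 rose adjusted over the list alone (median 0.76, camera adjusted p = 4.22e-06, adjusted p = 0.515 with an estimated correlation). The gut protease gene Jon74E stood at 37.6 ± 15.5 CPM in NSF and 111 ± 18.8 CPM in SF bodies (SD, n = 5, 1.56 ± 0.26, adjusted p = 0.0549), not past the test.

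Reproductive, sensory and detoxification lists rested in part on few libraries. Testis genes had 0 of 32 members past the test over all genes, and 5 rose adjusted over the list alone (median 0.59, camera adjusted p = 1.22e-07, adjusted p = 0.515 with an estimated correlation). Without aged NSF body 1, the library poor in betaTub85D, and body 2 the testis median was 0.29 (adjusted p = 6.28e-05), and 0.32 without aged NSF body 1. Of 26 male accessory gland genes, 0 passed over all genes and 0 changed adjusted over the list alone (median -0.49, camera adjusted p = 0.00231, adjusted p = 0.624 with an estimated correlation). It turned to 0.03 (adjusted p = 0.556) without aged NSF bodies 1 and 2, and was lost without aged NSF body 1 (0.187) or 2 (0.0791) or aged SF body 4 (0.137), with medians of -0.17 without aged NSF body 1 and -0.30 without aged SF body 4. Of 4 yolk genes 3 fell adjusted over the list alone and 0 over all genes. None of 19 phototransduction genes passed over all genes, and 6 fell adjusted over the list alone (median -0.37, camera adjusted p = 0.0313, adjusted p = 0.515 with an estimated correlation). Without aged NSF bodies 1 and 2 they stood at -0.07 (adjusted p = 0.337), and the call was lost without body 2 alone (0.387, median -0.08), aged SF body 2 (0.0545) or aged SF body 4 (0.0693). Glutathione S-transferase genes had 0 of 29 members past the test over all genes, and 1 rose and 3 fell adjusted over the list alone (median -0.30, camera adjusted p = 0.00122, adjusted p = 0.515 with an estimated correlation), with an adjusted p of 0.125 without aged NSF bodies 1 and 2. The transferase median moved to -0.19 without aged NSF body 1, -0.19 without aged SF body 4, and -0.17 without aged NSF bodies 1 and 2. Of 12 mitochondrial-genome genes, 0 passed over all genes and 0 changed adjusted over the list alone (median -0.20, camera adjusted p = 0.0143, adjusted p = 0.515 with an estimated correlation). That call moved to 0.221 without aged NSF bodies 1 and 2, 0.0767 without body 1 and 0.136 without aged SF body 4, and the median to -0.09 without aged SF body 4, and -0.13 without aged NSF bodies 1 and 2. None of 26 sleep regulators and 13 clock genes passed over all genes, and 1 sleep regulator rose adjusted over the list alone (camera adjusted p = 0.794 and 0.269).

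By edgeR 0 of 12009 genes had an adjusted p under 0.05, the smallest being 0.0549, and 2086 an unadjusted p under 0.05. DESeq2 gave 604 genes, limma voom with quality weights 385, and the list deposited by the authors has 441. For 796 genes the groups did not overlap, against a chance share of 0.79%. The edgeR count was 250 without aged NSF body 1, 21 without young body 1 and 6 without aged NSF body 2. It was 1 without any 1 of aged NSF bodies 4 and 5 and aged SF bodies 4 and 5, and 205 without aged NSF bodies 1 and 2 together.

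Fragmented sleepers against young flies complete the body comparisons. The peptide gene edin reached 63.5 ± 62.8 CPM (SD, n = 5), a ratio of counts of 413 (95% counting interval 141 to 2000). The attacin gene AttB rose from 14.3 ± 18.2 to 1182 ± 856 CPM (6.37 ± 0.97, edgeR adjusted p = 0.000615). Antimicrobial peptide genes rose in 12 of 14 cases and fell in none, and 12 rose adjusted over the list alone (median 4.48, camera adjusted p = 2.31e-11, adjusted p = 0.291 with an estimated correlation). The insulin receptor gene InR (2.21) rose here too.

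Muscle and nuclear respiratory genes were lower than in young bodies, and ribosomal genes higher. 19 of 25 muscle genes fell and none rose, and 22 fell adjusted over the list alone (median -0.92, camera adjusted p = 1.53e-20, adjusted p = 0.0699 with an estimated correlation). The sarcoplasmic calcium-binding protein gene Scp1 fell from 1056 ± 133 to 62.2 ± 20.2 CPM (SD, n = 5). Nuclear genes of oxidative phosphorylation fell in 47 of 81 cases and rose in none, and 61 fell adjusted over the list alone (median -0.63, camera adjusted p = 1.17e-25, adjusted p = 0.141 with an estimated correlation). Ribosomal protein genes rose in 20 of 87 cases and fell in none, and 30 rose adjusted over the list alone (median 0.28, camera adjusted p = 2.38e-06, adjusted p = 0.621 with an estimated correlation), and 6 rose with RLE scaling. Acp76A (-1.94), a serpin gene of the accessory gland, fell. The hemocyte gene Hml (-1.30) fell in bodies as well.

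In total 1727 of 12009 genes changed, 1336 higher and 391 lower, and 977 and 489 with RLE scaling. That excess of higher genes was lost without aged NSF body 1 (1629 and 1762) or with only the compared groups (1637 and 1732). Quality weights kept a smaller one (2247 and 1995). At least a 2-fold change was found for 610, and 1661 genes did not overlap between the groups, against a chance share of 0.79%. The count of changed genes was 3391 without aged NSF body 1, which is in the shared fit of the 3 groups, 1118 without young body 4 and 1087 without young body 5. Without aged NSF bodies 1 and 2 it was 3402, and with only the compared groups in the fit 3369.

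Whether normal-sleep ageing acted differently on head and body was tested as the interaction of tissue and group. Here rose and fell mean a change more positive or more negative in head than body. 67 of 87 ribosomal protein genes fell and none rose, and 78 fell adjusted over the list alone (median -0.74, camera adjusted p = 2.93e-20, adjusted p = 0.427 with an estimated correlation). With RLE scaling 31 of them fell. Mitochondrial-genome genes fell in 11 of 12 cases and rose in none, and 11 fell adjusted over the list alone (median -1.16, camera adjusted p = 1.1e-09, adjusted p = 0.246 with an estimated correlation). Bomanin and other Toll-induced peptide genes fell in 4 of 19 cases and rose in none, and 10 fell adjusted over the list alone (median -1.51, camera adjusted p = 5.01e-05, adjusted p = 0.427 with an estimated correlation). 11 of 25 synaptic genes fell and none rose, and 1 rose and 15 fell adjusted over the list alone (median -0.67, camera adjusted p = 7.5e-06, adjusted p = 0.315 with an estimated correlation). With RLE scaling 5 synaptic genes fell and 1 rose. Testis genes rose in 4 of 32 cases and fell in none, and 4 rose adjusted over the list alone (median 1.85, camera adjusted p = 1.24e-07, adjusted p = 0.427 with an estimated correlation), beside the low betaTub85D of aged NSF body 1.

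The gene with the smallest p was CG8343 (FBgn0040502, chromosome 2R, 6179726 to 6180356, plus strand), which went from 2427 ± 1175 to 0.979 ± 0.963 CPM in heads (SD, n = 5). Its interaction was -14.25 ± 1.31 (adjusted p = 3.13e-07), from a log2 fold change of -11.16 in heads and 3.08 in bodies. The dosage compensation helicase gene mle (1.81) and laza (-2.79), a lipid phosphatase gene of photoreceptors, also differed. Of 12318 genes 1622 differed between the tissues, 534 more and 1088 less in the head (edgeR, adjusted p under 0.05). RLE scaling moved the median of all genes from -0.09 to 0.12, a shift of 0.21, and the split to 833 and 534. The split also turned with DESeq2 (1238 and 727), and without young body 2 (749 and 381), 3 (674 and 317, 991 in all) or 5 (801 and 401), aged NSF body 3 (905 and 481) or aged SF body 1 (865 and 440) or 4 (901 and 467).

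The same interaction for fragmented against normal sleep asks whether head and body respond differently. By edgeR 0 of 12318 genes passed (smallest adjusted p 0.0816), 1259 had an unadjusted p under 0.05, and DESeq2 gave 123 and limma voom with quality weights 20. As lists, 2 families below stood lower in SF bodies than in SF heads, relative to normal sleepers, and digestive enzymes higher. None of 87 ribosomal protein genes passed over all genes, and 10 rose adjusted over the list alone (median 0.33, camera adjusted p = 1.56e-17, adjusted p = 0.289 with an estimated correlation). Heat shock genes had 0 of 19 members past the test over all genes, and 5 rose adjusted over the list alone (median 0.86, camera adjusted p = 8.91e-05, adjusted p = 0.289 with an estimated correlation). Of 39 digestive enzyme genes, 0 passed over all genes and 1 fell adjusted over the list alone (median -1.05, camera adjusted p = 3.2e-05, adjusted p = 0.289 with an estimated correlation). The count of genes was 13 without aged NSF body 1, 7 without aged SF head 2, 2 without aged NSF body 5 or aged SF body 5, and 12 without aged NSF bodies 1 and 2.

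Ageing changed many of the same genes in head and body. Among 8657 genes tested in both tissues, 674 were higher with age in both in normal sleepers, against 278 for independent lists, and 218 lower in both, against 103. Opposite changes were rarer than for independent lists, with 26 genes higher in the head and lower in the body (against 104) and 87 the reverse (against 276). In fragmented sleepers 510 were higher in both tissues, against 167, and 187 lower in both, against 36.0. Across genes, which are not independent replicates, the fold changes of head and body correlated with r = 0.529 for aged NSF against young, 0.553 for aged SF against young and 0.209 for aged SF against aged NSF.

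Antimicrobial peptide levels also differed between flies of a group. The mean log2 CPM of the 14 genes was 4.61 ± 1.49 in young, 9.87 ± 0.93 in aged NSF and 9.03 ± 1.12 in aged SF heads (SD, n = 5). In bodies it was 4.16 ± 1.32, 9.76 ± 0.94 and 8.49 ± 1.5. Taken as deviations from the group means, the scores of heads and of bodies with the same number correlated over 15 pairs with Pearson's r = 0.859 (permutation p = 9e-05, numbers permuted within conditions) and Spearman's rho = 0.864 (permutation p = 0.0001). Without the 2 pairs farthest from the median head score r was 0.866. Of 33 such relations, 1 per list, this had a Benjamini-Hochberg adjusted p of 0.0015.

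**Figure D5:**
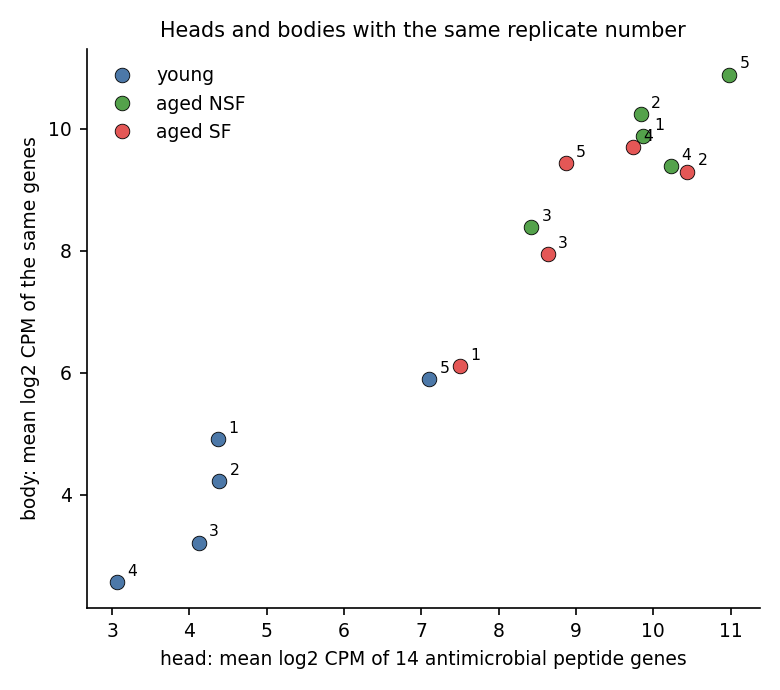
Mean log2 CPM of the 14 antimicrobial peptide genes in each head, on the horizontal axis, against the body with the same number, on the vertical axis, with 1 point per pair, its replicate number and a colour per condition. Young heads stand at 4.61 ± 1.49 and aged NSF heads at 9.87 ± 0.93 (SD, n = 5).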

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

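The tests of aged NSF body 1, the tests of the yolk transcripts of aged NSF body 2, the counts over other splits of the libraries and the margin used for traded labels were chosen after the result was seen. In 34 of 447 groups of 5 libraries (7.6%) 1 library stood far from the other 4, and chance alone marks about 1 in 20 such groups.

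Aged NSF body 1 has few testis transcripts, with a testis score of 3.16 against 5.42 to 5.79 in the other aged NSF bodies. Lower depth is argued against by 1 aged NSF body, number 2, with fewer reads (2458538 against 3615993) and a testis score higher by over 1 log2. A female fly or a wrong label for sex is argued against by the male accessory gland score of 7.87, within the 5.67 to 7.89 of the other bodies. Less testis tissue in the library stays open: 31 of 32 testis genes (96.9%) are lower than in the other aged NSF bodies, with a median deviation of -2.72 log2 (SD 0.942). Whether the fly had a smaller testis or the tissue was lost in preparation was not tested.

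Aged NSF body 2 has transcripts of photoreceptors and of yolk. Head RNA in this library may explain the photoreceptor part, since all of 18 head-specific genes chosen without it stand above the other aged NSF bodies, at a median of 1.996% of their head level (quartiles 1.41 and 2.49%). Male head RNA is argued against for the yolk part, as Yp1 would need 1682% of its level in aged NSF heads. Material of a female may explain it: Yp1, Yp2 and Yp3 stood at 10.4, 10.5 and 8.31 times the highest other body, so the lowest of the 3 ratios was 8.31. No biological explanation was tested, and Yp1 shares 54.3% of its exonic sequence with an overlapping gene.

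Trading aged NSF head 3 and aged SF head 5 between the groups gave 47 genes, against 23 as labelled. Swapped labels stay open only by the 1 SD margin chosen later. Held out, on a scale from 0 (aged NSF mean) to 1 (aged SF mean), aged NSF head 3 lies at 0.363, nearer its own group. It is above the other 4 (-0.021 to 0.321) and within 1 SD of them (0.174) of the midpoint. The 0.441 of aged SF head 5, nearer the aged NSF mean, goes with a single wrong label. It is below the other 4 (lowest 0.752), and undecided only by the margin, within 1 SD of them (0.217) of the midpoint. Aged NSF body 3 (0.338) and aged SF body 5 (0.643) lie on the sides of their labels. That speaks against whole flies traded only if equal numbers mark 1 fly. Milder fragmentation could also give 0.441, and no sleep values per fly are given to test it.

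Among marker genes per library, in CPM with the range of the other 4 in brackets, the distant values were ninaE at 31710.0 in young head 1 (17330.0 to 19010.0), ninaE at 324 in aged NSF body 2 (4.42 to 11.9), Arr2 at 119 in aged NSF body 2 (2.37 to 7.13), betaTub85D at 855 in aged SF body 4 (585 to 648), Act88F at 117 in aged SF body 5 (22.9 to 41.8) and Yp1 at 288 in aged NSF body 2 (11.9 to 28.2). Among list scores, in mean log2 CPM, they were Turandot and JAK-STAT at 8.03 in aged SF head 5 (8.50 to 8.65), sleep regulators at 5.62 in aged SF head 1 (5.53 to 5.55), synaptic genes at 8.1 in aged SF head 1 (7.94 to 7.99), insulin and FOXO at 5.72 in young head 4 (5.97 to 6.07), hemocyte at 4.45 in aged SF head 5 (5.03 to 5.18), Turandot and JAK-STAT at 7.17 in aged SF body 1 (6.58 to 6.75), clock at 5.77 in aged NSF body 2 (5.49 to 5.53), sleep regulators at 3.86 in aged SF body 3 (4.21 to 4.29), phototransduction at 5.41 in aged NSF body 2 (3.51 to 4.05), oxidative phosphorylation at 6.25 in aged NSF body 1 (6.72 to 6.91), glycolysis at 8.17 in aged SF body 4 (8.53 to 8.57), testis at 5.86 in young body 1 (6.46 to 6.55), testis at 3.16 in aged NSF body 1 (5.42 to 5.79) and yolk and eggshell at 6.25 in aged NSF body 2 (3.19 to 3.62). Among named genes, in log2 CPM, they were SPH93 at 0.29 in young head 5 (-0.30 to -0.30), IM23 at -0.30 in young head 1 (2.42 to 3.36), CG9757 at 5.89 in aged SF head 5 (3.70 to 3.96), Odc1 at 1.01 in aged NSF head 5 (2.39 to 2.90), Diedel at -0.30 in aged NSF head 4 (2.44 to 3.26), CG9676 at 0.33 in aged SF head 2 (-0.30 to -0.30), PGRP-SC2 at 4.69 in young head 5 (0.55 to 1.64), PGRP-SC2 at 7.71 in aged NSF head 3 (9.35 to 9.94), edin at 0.21 in young body 5 (-1.19 to -1.19), CG43920 at 1.08 in young body 5 (-1.19 to -0.75), Nplp3 at 8.56 in young body 5 (6.72 to 7.24), Scp1 at 4.84 in aged SF body 4 (5.89 to 6.25), Jon74E at 6.31 in aged SF body 4 (6.84 to 6.99) and Act79B at 6.94 in aged SF body 4 (7.73 to 8.05).

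Between head and body, 1622 genes differed in their change from young to aged NSF flies by the interaction test. The smallest adjusted p were those of CG8343 (-14.25, 3.13e-07), CG44774 (2.47, 1.59e-06), mle (1.81, 1.6e-06), CG42675 (2.69, 1.6e-06) and laza (-2.79, 2.36e-06). CG44774 shares 34.9% of its exonic sequence with an overlapping gene. Lists that differed in the same test, as medians of the head-minus-body log2 change, were Bomanins at -1.51, neuropeptides at -0.62, synapse and neuronal core at -0.67, phototransduction at -1.24, cytochrome P450 at -0.43, oxidative phosphorylation at -0.49, mitochondrial-genome genes at -1.16, cytosolic ribosomal proteins at -0.74, insulin and FOXO at -0.40, autophagy at -0.52, digestive enzymes of the gut at 1.32, fat body at -0.93 and testis and spermatogenesis at 1.85. For aged SF against aged NSF flies they were Bomanins at 0.71, immune recognition and NF-kB signalling at 0.28, Turandot stress peptides and JAK-STAT at 0.63, neuropeptides at 0.48, glia at 0.12, phototransduction at 0.32, heat shock proteins at 0.86, unfolded protein response at 0.23, glutathione S-transferases at 0.52, antioxidant enzymes at 0.094, oxidative phosphorylation at 0.29, cytosolic ribosomal proteins at 0.33, glycolysis at 0.22, digestive enzymes of the gut at -1.05, fat body at 0.46, testis and spermatogenesis at -1.30 and male accessory gland at 0.37. Without aged NSF bodies 1 and 2 those of P450 (-0.35, adjusted p = 0.0587) and fat body (-0.31, 0.19) were lost in the first test, where phototransduction moved to -0.66 (0.0119), and those of fat body (-0.18, 0.0804), phototransduction (0.02, 0.574), glia (0.10, 0.232) and accessory gland (-0.15, 0.974) in the second, where Turandot moved to 0.40, neuropeptides to 0.28, unfolded protein response to 0.14 and antioxidant enzymes to 0.26. In the first test RLE scaling moved oxidative phosphorylation to -0.29, insulin and FOXO to -0.21, autophagy to -0.34 and P450 to -0.24, and Turandot (0.0288) and odorant binding (0.0341) lists passed with it. None of the 13 and 17 list differences passed with an estimated correlation, where the smallest adjusted p was 0.246 and 0.0707. Testis, accessory gland and gut values mostly restate bodies.

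Chance as the source of the gene counts was weighed with other splits of the same libraries into groups of 5, the real split counted among 100 drawn of 126 (50 of 31752 for the interactions). Chance can be excluded for aged NSF against young heads (2075 genes, highest other split 87, 1 split with as many), aged SF against young heads (2293, 230, 1), the same comparisons of bodies (4934, 10, 1 and 1727, 140, 1) and the interaction of aged NSF against young (1622, 462, 1 of 50). For aged SF against aged NSF heads few splits had as many as the 23 genes (2 of 100), and chance is not excluded there either. The traded split gave 47. At an unadjusted p under 0.05 the real split, with 848 genes, was not the highest (910, 3 splits with as many). Aged SF against aged NSF bodies and the interaction of the same groups had 0 genes, so that all 100 and 50 splits have as many and the count decides nothing (highest other 84 and 6). The split with 84 genes trades aged NSF body 1 and aged SF body 4 and points to a structure of the samples. At an unadjusted p under 0.05 the real split of those bodies gave 2086 genes (highest other 1456, 1 split with as many) and the real interaction 1259 (1332, 2 of 50).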

How the results depend on the processing

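Leaving out aged NSF bodies 1 and 2 together was chosen after the data were seen. Aged NSF against young heads kept its count within 1.5 times under every alternative except the 2-fold minimum (883 genes), and so did aged SF against young heads (913) and aged NSF against young bodies (2610); with single libraries left out their ranges were 1732 to 2119, 1928 to 2377 and 3644 to 5339. Aged SF against aged NSF heads (23 genes) gave 86 with DESeq2, 56 without a filter, 39 with quality weights, 36 with only the compared groups and 9 to 61 with single libraries left out; the 23 genes are all among those of DESeq2 and of the unfiltered test. Aged SF against aged NSF bodies (0 genes) gave 604 with DESeq2, 385 with quality weights, 5 with RLE scaling, 5 with the stricter filter, 1 without one, 205 without aged NSF bodies 1 and 2 and 0 to 250 with single libraries left out. Aged SF against young bodies (1727) gave 610 at 2-fold, 4242 with quality weights, 3369 with only the compared groups, 3402 without aged NSF bodies 1 and 2 and 1087 to 3391 with single libraries left out. The interaction of aged NSF against young (1622) gave 964 at 2-fold and 991 to 1885 with single libraries left out, and that of aged SF against aged NSF (0) 123 with DESeq2, 20 with quality weights, 12 without aged NSF bodies 1 and 2 and 0 to 13 with single libraries left out. The correlation of aged SF against aged NSF changes between head and body, 0.209, ranged from 0.138 to 0.265 with single numbers left out. Except where the setting itself lowers the number of genes or samples, the cause was not tested.

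With the replicate number as a block, the counts moved from 23 to 63 in aged SF against aged NSF heads and from 0 to 1 in the bodies, and in the interaction, with condition and number as the block, from 0 to 3; the other counts stayed within 1.5 times (2234, 2472, 5261, 1647 and 1978). Of 15 heads 13 correlated best with the body of their own number, a hint from the data, not the design.

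Of 12118 results for single named genes under the alternatives, 11560 kept direction and side of the threshold, 511 dropped below it, 47 rose past it and 0 turned; of 3886 list results the numbers were 3551, 212, 121 and 2. Both tests that turned are of the accessory gland list without aged NSF bodies 1 and 2: 0.029 (adjusted p = 0.556) against -0.489 in bodies, aged SF against aged NSF, and -0.146 (adjusted p = 0.974) against 0.367 in the interaction. Among lists past the threshold with or without the change of setting, medians alone changed sign for odorant binding proteins without aged SF head 3 (-0.049 against 0.277 in heads, aged SF against aged NSF) and, in the same interaction without those bodies, fat body (-0.18 against 0.456) and proteasome (0.112 against -0.008). Smaller changes are often missed, as the simulated changes of 1 log2 given above show.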

Other observations

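The comparison of same-numbered heads and bodies in the antimicrobial peptide score and across all genes, given below as tests, was chosen after the result was seen. Stress and metabolic lists vary between flies as well. As deviations from the group means over the 15 same-numbered pairs, the scores of head and body correlated for antioxidant enzymes (r = 0.88, permutation p = 7e-05, rho = 0.886 with permutation p = 8e-05, adjusted p = 0.0015, r = 0.847 without the 2 farthest pairs), and also for glycolysis (r = 0.757, permutation p = 0.0026, rho = 0.8 with permutation p = 0.0018, adjusted p = 0.024, r = 0.634 without the 2 farthest pairs), fat body genes (r = 0.746, permutation p = 0.0036, rho = 0.675 with permutation p = 0.013, adjusted p = 0.024, r = 0.615 without the 2 farthest pairs) and heat shock genes (r = 0.612, permutation p = 0.0029, rho = 0.654 with permutation p = 0.012, adjusted p = 0.024, r = 0.608 without the 2 farthest pairs). The proteasome list (r = 0.676, permutation p = 0.005, rho = 0.657 with permutation p = 0.023, adjusted p = 0.028, r = 0.778 without the 2 farthest pairs) and the autophagy list (r = 0.713, permutation p = 0.0077, rho = 0.589 with permutation p = 0.028, adjusted p = 0.036, r = 0.569 without the 2 farthest pairs) complete the 7 of 33 relations, the antimicrobial peptides included, with an adjusted p under 0.05.

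Some genes had few or no reads at 1 age. In young heads no read was found for the cuticle genes Cpr47Eb and Cpr49Ac and for CG9757, which were at least 4.03, 9.25 and 13.2-fold higher in aged NSF heads, against 3 counts per library, and for the cuticle genes at least 5.29 and 13.9-fold in aged SF heads. CG11370 had 2 reads in young heads, and aged SF heads stood 626 times higher (95% counting interval 173 to 5170). In bodies the larval storage protein gene Lsp1gamma kept 2 reads in aged NSF flies, with young flies 53 times higher (14.4 to 442), and the mitochondrial tRNA gene mt:tRNA:I was at 0 in young bodies and at least 5.2-fold higher in aged NSF bodies.

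A candidate explanation for flies that differ within a group in their antimicrobial peptide levels is that the head and the body with 1 number come from 1 fly, and so share its immune state. The Pearson r of 0.859 over 15 pairs goes with it, and so does the mean correlation of same-numbered pairs across 8657 genes, 0.162 (highest of the permuted means 0.149), and across 8597 genes without the immune lists, 0.148 (highest permuted 0.145), each with a permutation p of 1e-05, the smallest that the permutations can give. A shared vial or handling order of the same numbers could give these values too and was not tested.

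The correlation between the head and body changes of aged SF against aged NSF flies, r = 0.209 across genes, was set beside other splits of the aged libraries. With the same numbers moved in head and body, 25 of 100 splits were as high (highest other 0.399), so that chance in the grouping of the flies can give it and cannot be excluded. With head and body split independently 3 of 100 were as high (highest other 0.278).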
